A study of Homo sapiens with 2 samples.

How the data were processed

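Total RNA from MCF-7 cells was measured on 1-colour arrays, with 1 array for sh-scrambled and 1 for sh-CCN5. Per the labels, the RNA was extracted with a column kit, amplified by in vitro transcription and labelled with biotin. The values used were the probe intensity on a linear scale, as deposited by the authors. The scanner software, background correction, scaling between arrays and reason for empty cells are not given in the sources used here. Of the 54359 probes, 54.4% had an empty cell on sh-scrambled and 53.7% on sh-CCN5, and 25821 were empty on both. Probes listed on 1 array alone were mostly dim, with medians of 1.69 on sh-scrambled and 1.64 on sh-CCN5, and 5.15% and 4.55% of them reached 10. The unit behind the intensities stays unknown, so they are given as deposited and compared between arrays within a probe.

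Probes were named with the platform annotation, which gave 1 gene for 23472 probes, several for 905 and none for 29982. Of the single-gene probes, 23434 were matched by gene identifier to a RefSeq table of assembly GRCh38.p14, and 0 symbols needed an update. That table served for names and for the order of genes along chromosomes, and no coordinates are given because the deposited values name no genome build. Probes with several genes were left out, which removed VIM. A gene was represented by the probe with the highest mean log2 level, and 10560 of 18278 genes had a probe listed on both arrays.

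On each array, values under the 10th percentile of its listed values (1.47 on both) were set to that percentile, and log2 was taken. The quartiles of the arrays on the log2 scale (1.07, 2.07 and 3.59 on sh-scrambled, 1.05, 1.99 and 3.49 on sh-CCN5) agreed within 0.1, and by the rule set for that case the deposited scaling was kept. The median difference was -0.01 over all probes listed on both arrays and -0.08 over genes at the level filter. The level filter was a mean log2 level at or above the median of all probes listed on both arrays (2.32), which left 6586 genes. Genes were counted as higher or lower at a difference of at least 2-fold, a rule of size and not a test. Log2 values of the arrays correlated at r = 0.897 across probes. As a description of the scatter between arrays, the scaled median absolute deviation of the differences of the 501 probes nearest in level was used, with a median of 0.64 over genes at the filter (0.25 to 0.77). For each of 34 gene lists, the median difference over members at the filter was set against 10000 random lists of the same size, matched on level in 20 bins.

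The design, the level filter, the lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. The rule named CCN5, then 10 fixed genes (TGFBR2, TGFBR1, ESR1, PGR, CDH1, VIM, SNAI1, SNAI2, TWIST1 and ZEB1), then the 12 genes with the highest and the 12 with the lowest difference at the filter, and then, for each list described, up to 2 members at each end. Genes outside the rule were named after their values were seen. The written design did not foresee empty cells. Genes with a value on 1 array alone were therefore given with that value and no fold, and a fill of empty cells with the floor was added as an alternative after the data were seen. The other alternatives were quantile normalization, median centring, a loess correction with a span of 0.3, the median of all probes of a gene, log2 of the value plus 50, no level filter, a filter at the 75th percentile, other size thresholds, and random lists not matched on level.

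The lists covered the CCN family, TGF-β components and targets, epithelial, mesenchymal, estrogen receptor target, luminal, basal and stem-like genes, collagens, matrix proteases, integrins, G2 and mitosis, G1/S, p53 targets, interferon response, NF-kB, immediate-early genes, hypoxia and glycolysis, cholesterol synthesis, unfolded protein stress, heat shock, apoptosis, Notch, Wnt, growth factors, histone deacetylases, small RNA machinery, ribosomal proteins, histones, oxidative phosphorylation, and markers of fibroblasts, immune and endothelial cells. The position lists held 20 genes at 17q23 and 30 at 20q13, without BCAS3, whose value had been seen. They were written after the first results were known and before their own medians were. TFAP2C and AURKA at 20q13 were also members of the luminal list and of the G2 and mitosis list. The values of both genes were thus already among the first results, and both were kept at 20q13.

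Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for the plots. The procedure was tested on simulated data of 1 array against 1 array with 6584 genes and an SD of the log2 difference of 0.3. Only probes listed on both arrays were simulated, and the changed genes lay at least 1 log2 unit above the level filter. Losses to empty cells were therefore not covered, and losses to the filter hardly so. Within these limits the procedure recovered 95% of genes changed by 1.5 and 100% of those changed by 2.5 on the log2 scale. It counted 0.0786% of unchanged genes as at least 2-fold different. With the SD set to 0.64, the median scatter measured between these arrays, which holds real differences too, it recovered 85% and 98%, and counted 12.03% of unchanged genes. A simulated list shifted by 0.8 lay at the 100th percentile, and 5.56% of 216 unshifted list draws lay outside the central 95%. The simulated genes varied independently, so this does not cover real lists, whose members can be correlated. Percentiles against random lists take no account of such correlation. The simulation does not know the true spread between cultures, which 1 array per group leaves unmeasured.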

Results

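Gene expression was measured in MCF-7, a luminal and estrogen receptor-positive human breast cancer cell line, with 1 array for cells carrying a short hairpin RNA against CCN5 (sh-CCN5) and 1 array for cells carrying a scrambled hairpin (sh-scrambled). Of 54359 probes, 24779 had an intensity on the sh-scrambled array and 25178 on the sh-CCN5 array, 21419 of them on both. The listed intensities ran from 0.829 to 1474 with a median of 4.19 on sh-scrambled, and from 0.886 to 1197 with a median of 3.98 on sh-CCN5. With 1 array per group there was no replicate, so no difference could be tested, and the number of arrays limits the precision of every value. Differences are given as log2 of sh-CCN5 over sh-scrambled and describe these 2 arrays.

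The series asks whether CCN5 acts as a repressor of transcription. The comparison shows which transcripts differed between the sh-CCN5 and sh-scrambled arrays. With 1 array per group, it cannot assign a difference to the hairpin. CCN5, a secreted matricellular protein also known as WISP2, had an intensity of 3.66 on sh-scrambled and 1.479 on sh-CCN5, a log2 difference of -1.31 (2.47-fold lower). Its only probe lay below the level filter, and its sh-CCN5 value lay near the floor of 1.47 set for that array, so the fold is bounded by the dim end of the scale. The scatter of probes at that level was 0.45 on the log2 scale. The floor limits how far any probe at that level can differ, so this scatter cannot serve as a yardstick for the fold.

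TGFBR2, the type II receptor for TGF-β, is a gene of interest in work on CCN5. Both of its probes were listed on sh-CCN5 alone, at intensities of 23.7 and 6.96, and had empty cells on sh-scrambled. TGFBR1, the type I receptor, had empty cells on both arrays. ESR1, which encodes estrogen receptor α, had an intensity of 69.1 on sh-scrambled and no value on sh-CCN5. PGR, the progesterone receptor gene and a target of that receptor, had a value from 1 of its 3 probes, 1.33 on sh-CCN5, under the floor of 1.47. Among transcription factors that repress epithelial genes, SNAI2 (21.3, from 1 of its 2 probes, the other being empty on both arrays) and ZEB1 (8.27) were listed on sh-CCN5 alone, SNAI1 (2.64) on sh-scrambled alone, and TWIST1 on neither array. CDH1 and VIM had no probe annotated to them alone and were not analysed here. An empty cell is not a measured absence: HSP90AB1, an abundant cytosolic chaperone named after its values were seen, had an intensity of 152 on sh-CCN5 and no value on sh-scrambled.

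Among 6586 genes at or above the level filter, 628 were at least 2-fold higher and 968 at least 2-fold lower on sh-CCN5, and 67 and 88 of these were at least 8-fold higher and lower. With 50 added to every intensity before log2, 31 and 52 genes remained past 2-fold, and in simulated arrays with the scatter measured here, 12.03% of unchanged genes passed 2-fold. PLAUR, the receptor that holds urokinase at the cell surface, had the highest difference, with intensities of 1.95 on sh-scrambled and 128 on sh-CCN5 (log2 6.04, 65.6-fold). EMP3, a membrane protein, was 63.4-fold higher (2.43 and 154) and CAVIN3, a component of the caveolar coat, 63.0-fold higher (1.85 and 117). Genes induced by interferon were also among the 12 highest, with IFIT3 at 61.9-fold, HERC5 at 43.1-fold and OASL at 31.7-fold higher. SLC43A3, a nucleobase transporter, was 46.9-fold higher, the actin-capping protein CAPG 38.1-fold, the BH3-only death protein PMAIP1 36.5-fold and the chemokine CXCL8 29.4-fold higher. The sh-scrambled values of SLC43A3 (1.57), CXCL8 (1.72), CAVIN3 (1.85), CAPG (1.87), PLAUR (1.95) and IFIT3 (1.95) lay near the floor of 1.47. Their folds are therefore bounded by the dim end of the scale. PHLDA1, a growth factor-induced gene, and SDHAF3, an assembly factor of succinate dehydrogenase, had log2 differences of 5.27 and 4.98 with sh-scrambled values at the floor, so their folds are set by the floor.

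BCAS3, a gene at 17q23 named for its amplification in breast cancer, lay lowest, at 132 on sh-scrambled and 1.96 on sh-CCN5 (log2 -6.07, 67.1-fold lower). FOXA1, the pioneer factor that opens chromatin for estrogen receptor α, was 64.9-fold lower (138 and 2.12). STARD10, a phospholipid transfer protein, was 34.4-fold lower, CREB3L4, a transcription factor anchored in the endoplasmic reticulum, 33.1-fold lower, and CRABP2, which carries retinoic acid, 29.2-fold lower. The sterol reductase gene TM7SF2 was 28.6-fold lower, the trafficking gene TRAPPC6A 28.1-fold, the GDNF co-receptor gene GFRA1 27.5-fold, the junction protein gene JUP 25.2-fold, the phosphatase gene DUSP2 23.7-fold and the collagen receptor gene DDR1 22.7-fold lower. KRTCAP3 had a log2 difference of -4.60 with its sh-CCN5 value at the floor. The sh-CCN5 values of DUSP2 (1.64), TM7SF2 (1.96) and BCAS3 (1.96) lay near the floor, which bounds their folds as well. Across 605 genes with a second probe at that level, the differences of both probes correlated at r = 0.704 across genes, which are not independent replicates, and in 126 of 139 genes whose brighter probe differed at least 2-fold the other probe had the same sign.

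**Figure D1:**
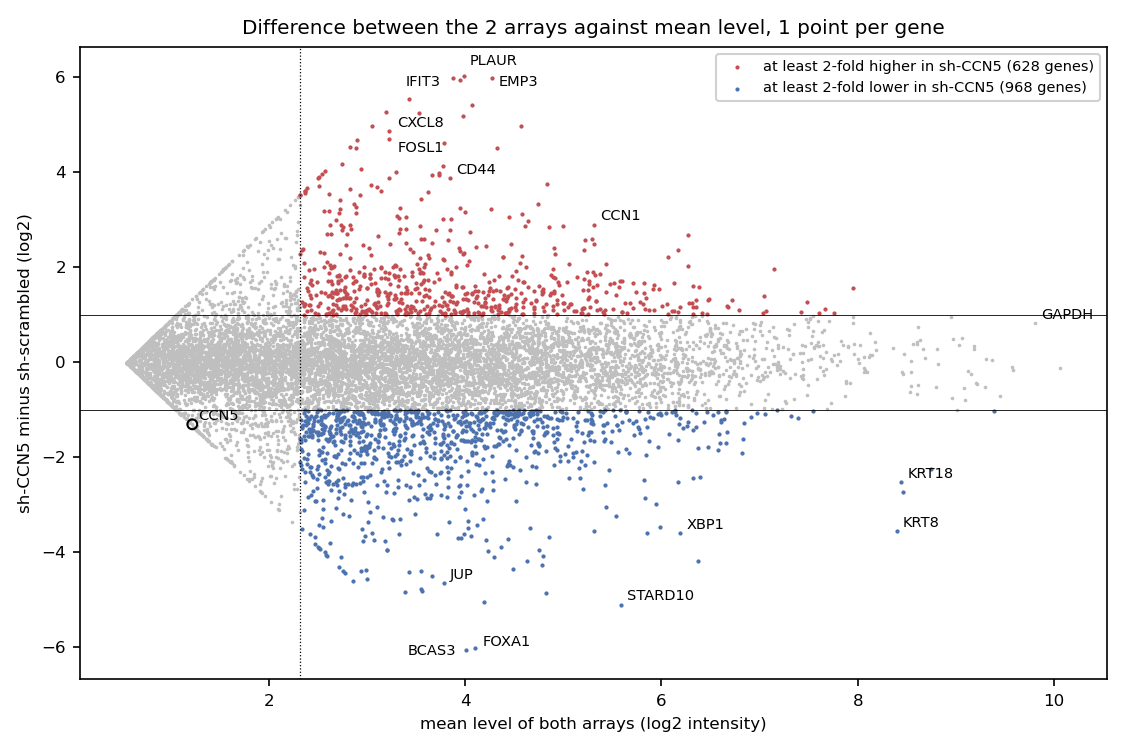
Log2 difference between the sh-CCN5 and sh-scrambled arrays (vertical axis) against the mean log2 intensity of both arrays (horizontal axis), with 1 point per gene listed on both arrays. Red and blue points are the 628 and 968 genes at least 2-fold higher and lower at or above the level filter of 2.32 (dotted line), and CCN5 is circled at -1.31, below that filter.

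Luminal and epithelial genes were lower on sh-CCN5. Of 11 luminal breast identity genes at the level filter, 11 were at least 2-fold lower, with a median log2 difference of -2.68. Beside FOXA1, they included CA12, a carbonic anhydrase (log2 -4.39), and XBP1, a transcription factor of secretory cells (254 and 20.9, log2 -3.601). Of 13 epithelial junction and identity genes, 12 were at least 2-fold lower and 1 lay within 2-fold, with a median of -2.32. The keratin gene KRT8 had intensities of 1159 and 98.3 (log2 -3.56), and TJP1, which encodes a tight junction scaffold, was the exception at 0.10. Of 14 estrogen receptor target genes, 9 were at least 2-fold lower, 0 higher and 5 within 2-fold, with a median of -1.74. That median was -3.44 over 21 genes with empty cells filled with the floor, and -1.40 over 6 genes with the filter at the 75th percentile. RERG, a growth-inhibiting small GTPase (log2 -4.41), lay lowest with CA12, and IGFBP4, a binding protein of insulin-like growth factors (0.77), and MYBL1 (0.51) lay highest. At the level filter, each of the 3 list medians lay below all 10000 random lists matched on level. The lists share members, such as KRT8 (luminal and epithelial) and CA12 (luminal and estrogen receptor target), so these medians are not independent.

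Several of the brightest members of these lists, named after their values were seen, were listed on sh-scrambled alone. They were the keratin gene KRT19 (1239), the secreted peptide gene TFF1 (240), the claudin gene CLDN3 (99.8), the luminal transcription factor gene SPDEF (71.9) and RAB25, which encodes a GTPase of epithelial recycling (59.1). In all, 7 luminal, 7 epithelial and 9 estrogen receptor target genes had a value on sh-scrambled alone, against 1, 2 and 1 on sh-CCN5 alone.

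**Figure D2:**
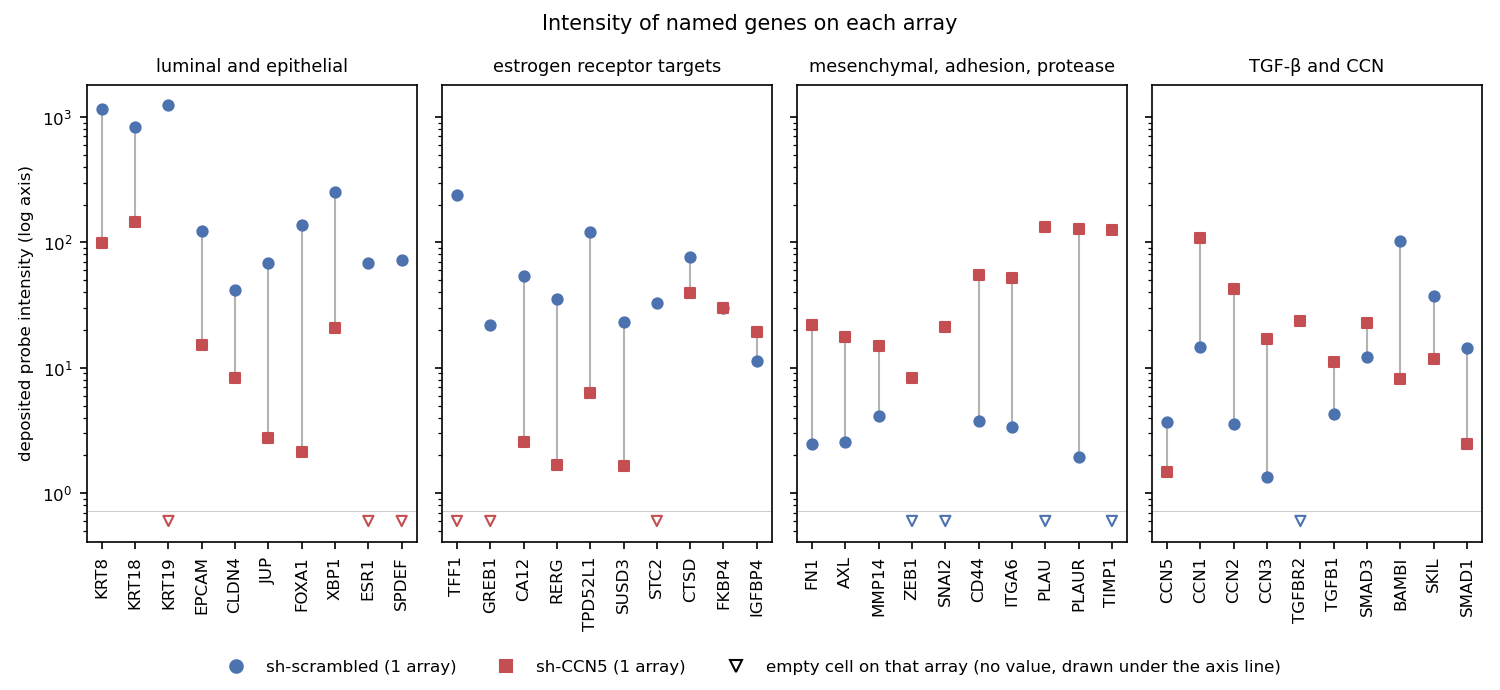
Deposited intensity (log axis) of 40 genes on the sh-scrambled array (blue circles) and the sh-CCN5 array (red squares), with 1 array each. Open triangles under the grey line mark an empty cell, as for KRT19 (1239 on sh-scrambled alone) and PLAU (132 on sh-CCN5 alone).

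Lists of mesenchymal, matrix protease and integrin genes had members at least 2-fold higher on sh-CCN5 and 0 at least 2-fold lower at the level filter, with up to 6 within 2-fold. Of 4 mesenchymal genes at the level filter, 3 were at least 2-fold higher and 1 within 2-fold, with a median of 2.32. The matrix gene FN1 (log2 3.15) and the receptor kinase gene AXL (2.79) lay highest, and the tropomyosin gene TPM2 lay at -0.20. A further 6 members were listed on sh-CCN5 alone, 2 on sh-scrambled alone and 13 on neither. With the filter raised to the 75th percentile TPM2 alone was left, which turned the median to -0.20. Of 11 matrix proteases and inhibitors, 5 were at least 2-fold higher, 0 lower and 6 within 2-fold (median 0.92, above 99.9% of random lists), with 6 members listed on sh-CCN5 alone and 2 on sh-scrambled alone. Beside PLAUR these included the protease inhibitor gene SERPINE2 (3.22), while CTSD, which encodes a lysosomal protease, lay at -0.94 and the sheddase gene ADAM15 at -0.05, a value that turned slightly positive, to 0.02 and 0.03, with quantile and median scaling. Urokinase itself, PLAU, and the metalloprotease inhibitor TIMP1 were listed at 132 and 125 on sh-CCN5 alone, and were named after their values were seen. Of 8 integrins and CD44, 5 were at least 2-fold higher, 0 lower and 3 within 2-fold, with a median of 1.65, above all random lists. ITGA6, a laminin receptor subunit, had intensities of 3.40 and 52.3 (log2 3.94), and CD44, the hyaluronan receptor, 3.75 and 55.2 (log2 3.88).

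Of 5 basal and myoepithelial genes, 2 were at least 2-fold higher, ITGA6 and CD44, and 3 within 2-fold, CDH3 at -0.93 being the lowest, with a median of 0.87 at the 98.5th percentile of random lists, and 5 members were listed on sh-CCN5 alone against 1 on sh-scrambled alone. Of 8 stem-like genes, which share ITGA6 and CD44 with these lists, 5 were at least 2-fold higher, 1 lower and 2 within 2-fold, with a median of 3.14, above all random lists; the chemokine receptor gene CXCR4 was the lower member (-2.38). Of 4 collagen and basement membrane genes, 2 were at least 2-fold higher and 2 within 2-fold, with a median of 0.65 at the 95.5th percentile, inside the central 95% of random lists. COL13A1, a transmembrane collagen gene, had a difference of 4.03 from a value at the floor, and the laminin chain gene LAMA5 1.02, with another probe at 0.68, within 2-fold.

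Other members of the CCN family were higher where CCN5 was lower. CCN1, CCN2 and CCN3, secreted matricellular genes, were the 3 members at the level filter, with differences of 2.90, 3.596 and 3.52 and a median above all random lists, the sh-scrambled value of CCN3 being at the floor. CCN4 and CCN6 had no value on either array. CCN2 had intensities of 3.53 and 42.7, and CCN1, named after its values were seen, 14.6 and 109.

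TGF-β ligands, receptors and SMADs showed no common direction. Of 13 at the level filter, 1 was at least 2-fold higher, 3 were lower and 9 within 2-fold, with a median of 0.07 at the 74.0th percentile of random lists. With the filter at the 75th percentile, 4 genes remained and their median was -1.13. The ligand gene TGFB1 (1.36) and the signal transducer gene SMAD3 (0.91) lay highest, and BAMBI, a decoy receptor (103 and 8.10, log2 -3.67), and SMAD1, a transducer of BMP signals (-2.52), lowest. A further 4 members were listed on sh-scrambled alone and 3 on sh-CCN5 alone. The former included the inhibin subunit gene INHBB (73.9), named after its value was seen, and the latter TGFBR2 (23.7). Of 9 TGF-β target genes, 2 were at least 2-fold higher, 3 lower and 4 within 2-fold, with a median of -0.53 at the 7.495th percentile. That median was -0.077 over 18 genes without the filter and -0.96 over 3 genes with the filter at the 75th percentile. CCN2 (3.596) and FN1 (3.15) lay highest, and SKIL, which dampens SMAD signalling (-1.67), and the AP-1 gene JUNB (-1.42) lowest.

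**Figure D3:**
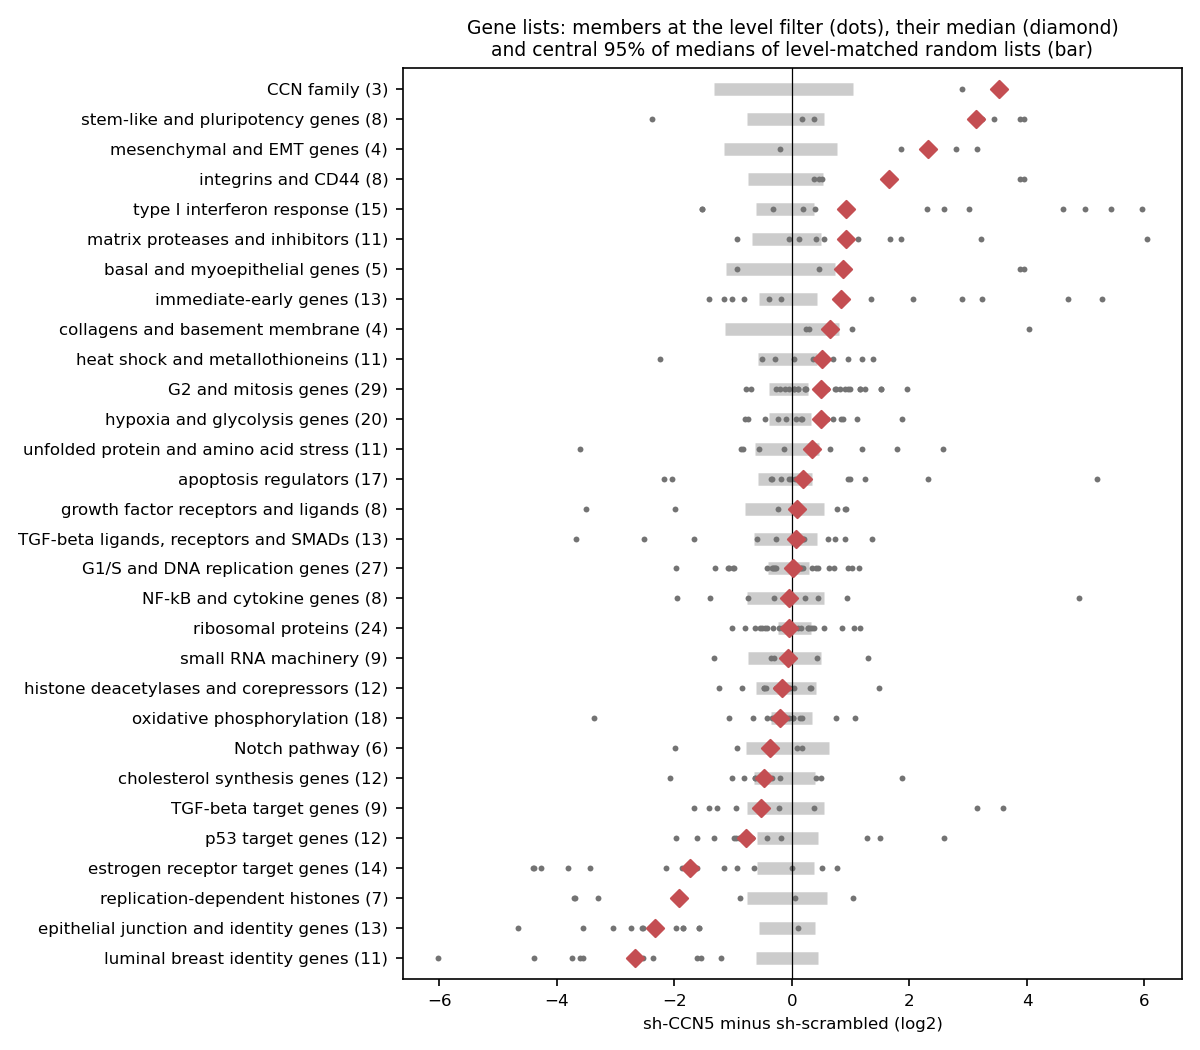
Log2 difference between the sh-CCN5 and sh-scrambled arrays for the members of each gene list at the level filter (grey dots, their number in brackets), their median (red diamond) and the central 95% of medians of 10000 random lists matched on level (grey bar), for lists with at least 3 such members. The luminal median of -2.68 and the CCN family median of 3.52 mark the ends of the range.

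Interferon response genes split. Of 15 at the level filter, 7 were at least 2-fold higher, 2 lower and 6 within 2-fold, with a median of 0.93, above 99.99% of random lists. That median was 0.62 over 22 genes without the filter and 2.58 over 11 genes with the filter at the 75th percentile. A further 3 members were listed on sh-scrambled alone, BST2 (52.1) among them, and 3 on sh-CCN5 alone, IFI44 (94.3) among them. BST2 and IFI44 were named after their values were seen. IFIT3 (5.95) and HERC5 (5.43) lay highest, and PARP9, a macrodomain gene (-1.54), and IRF9, the DNA-binding subunit of the interferon-activated complex (-1.53), lowest. Of 13 immediate-early genes, 6 were at least 2-fold higher, 3 lower and 4 within 2-fold, with a median of 0.83 (above 99.95% of random lists). The AP-1 members FOSL1 (4.70) and FOS (-1.16) lay on opposite sides, with PHLDA1 at the top and JUNB at the bottom. Of 29 G2 and mitosis genes, 6 were at least 2-fold higher and 23 within 2-fold, with a median of 0.49, above 99.96% of random lists. CDC20, an activator of the anaphase-promoting complex (1.96), and the kinesin gene KIF2C (1.52) lay highest, and MYBL2 (-0.78) and HMMR (-0.69) lowest. Of 27 G1/S and DNA replication genes, 2 were higher, 5 lower and 20 within 2-fold, with a median of 0.02 at the 69.5th percentile.

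Differences also followed gene position. Of 14 genes at 17q23, a region known to be amplified in MCF-7, 11 were at least 2-fold lower on sh-CCN5, 1 was higher and the median was -2.72, below all random lists. PPM1D, a phosphatase gene of that region, had intensities of 79.3 and 5.37 (log2 -3.88), and TRIM37, a ubiquitin ligase gene, a difference of -3.72, while PRR11 (1.30) and SKA2 (0.47) lay on the other side. The members named here were chosen after their values were seen. Of 18 genes at 20q13, also amplified in MCF-7, 6 were at least 2-fold lower and 2 higher, with a median of -0.46 at the 3.03rd percentile, inside the central 95% of random lists. A further 4 of its genes were listed on sh-scrambled alone, SULF2 (25.3), PTPN1 (11.99), BMP7 (11.8) and BCAS1 (6.73), and 1 on sh-CCN5 alone, CYP24A1 (1.85). Across 6577 genes in chromosomal order, the difference of a gene correlated with the median difference of genes 5 to 15 places away at r = 0.283, against -0.039 to 0.030 in 100 shuffles of gene order. The gene groups above were read from the same 2 arrays. With 1 array per group, their differences cannot be told apart from other differences between the cells, such as different sets of gene copies. They cannot be assigned to the hairpin from these arrays alone.

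**Figure D4:**
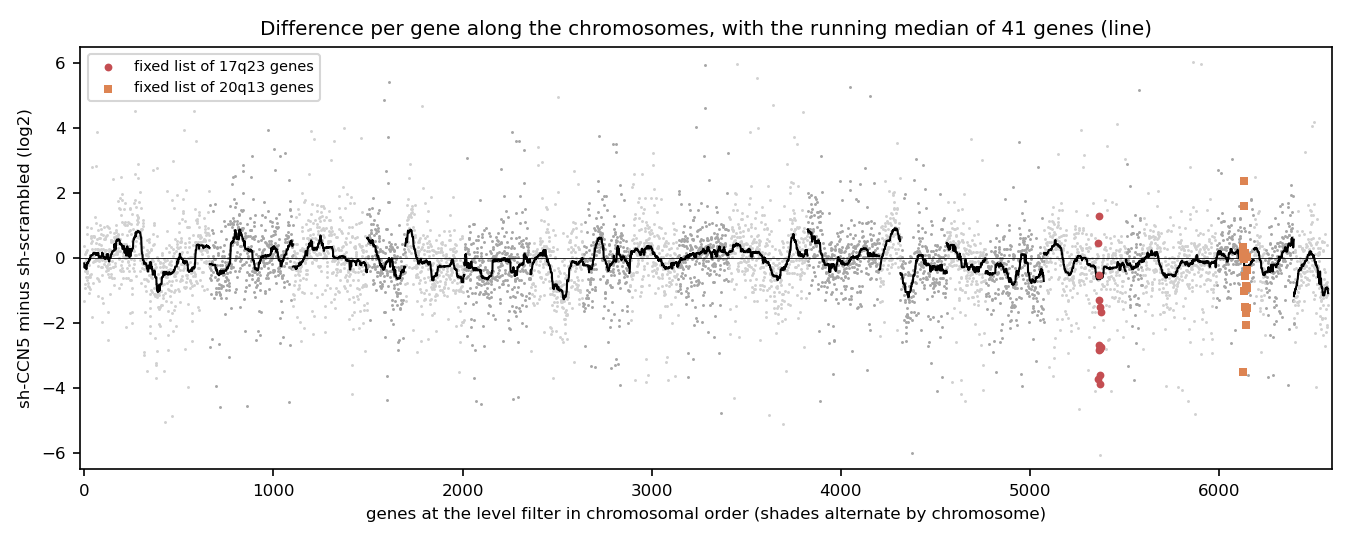
Log2 difference between the sh-CCN5 and sh-scrambled arrays for 6577 genes in chromosomal order (grey dots, shades alternating by chromosome), with the running median of 41 genes (line) and the genes at 17q23 (red circles) and 20q13 (orange squares). The running median lay between -1.27 and 0.91 where a full window of genes was present, and the 17q23 genes had a median of -2.72.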

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

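The share of empty luminal probes, the variants of the gene-order test, the test on fibroblast markers and the choice of the other-probe test came only after the results were seen, while the bounds of the other-probe test were set before its value was computed.

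Luminal and epithelial genes and 3 of the 4 mesenchymal genes at the level filter lay on opposite sides on the sh-CCN5 array. The quartiles of the arrays already agreed within 0.1, so quantile and loess scaling had little room to change this. The tables argue against scaling as the whole cause, since the gap between the mesenchymal and luminal medians was 4.997 and stayed at 4.98 or more under both scalings. They also argue against admixed fibroblasts as the whole cause, for the markers with a value. Dilution to the luminal median of -2.68 needs a share of 84.4%. Of 14 fibroblast markers with a probe, the 6 with a value on sh-CCN5 reached at most 7.35 (C1S), against a 90th percentile of 32.7. COL1A1 lay at 3.51 and 3.70, and PCOLCE was lower, at 14.5 and 2.57. COL1A2, COL3A1, DCN and LUM were empty on sh-CCN5, which is not a measured absence, and a small admixture stays open. A candidate explanation is that the cells of the 2 arrays carried different sets of gene copies, as a mix-up, another line or a diverged subline might: the median of 32 genes from the MCF-7 amplicons was -1.14, against -0.37 to 0.25 in the central 95% of random lists (20q13 alone, at -0.46 over genes at the filter, lay inside its range), and the correlation with neighbouring genes was 0.283, or 0.290 without chromosomes 17 and 20, 0.247 with genes 16 to 30 places away and 0.295 without the genes of the 34 lists. Neighbouring genes can also be regulated together, and no reference for that was used here. A test on CDKN2A and MTAP, genes taken to be deleted in MCF-7, left the matter open with 0 of the pair gained. CDKN2A was empty on both arrays. MTAP was listed on both (8.33 and 12.4), above the array medians of 4.19 and 3.98, so its deletion in these cells could not be taken as given. An effect of CCN5 depletion was not tested apart from these explanations, since 1 array per group ties it to any other difference between cells. The sh-CCN5 differences above cannot be assigned to the hairpin from these arrays alone.

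Of 23 probes of the luminal and estrogen receptor target lists with at least 20 units on sh-scrambled, 5 were empty on sh-CCN5, or 21.7% (exact 95% interval 7.46 to 43.7), against 51 of 2804 other named probes, or 1.82% (1.36 to 2.38); the intervals cover counting error only, and the lists were picked because members had been seen empty. Spots lost at random were therefore tested on genes with another probe listed on both arrays, over all genes. That other probe had a median difference of -0.55 in 28 genes with a probe empty on sh-CCN5 and 0.34 in 23 genes with a probe empty on sh-scrambled, a gap of -0.89 against -0.48 to 0.48 in the central 95% of 10000 random draws, which argues against random loss as the source of all empty cells. Loss unrelated to expression stays open for single genes, as 1.89% of probes of at least 20 on sh-CCN5 were empty on sh-scrambled, HSP90AB1 among them. No biological explanation was tested for the empty cells.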

How the results depend on the processing

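The setting that fills empty cells with the floor was chosen only after the data were seen. No paired analysis was possible because each group had 1 array, and for the same reason leaving out a replicate could not be run. Quantile, median and loess scaling kept the counts of higher and lower genes within 1.5 times, at 731 and 834, 706 and 854, and 650 and 931, and moved 1 of the 34 list medians, that of the ribosomal proteins, to 0.23 under quantile scaling. Medians near 0 changed sign with scaling for the ribosomal, NF-kB and small RNA lists. Adding 50 to each value shrank differences by construction, since most intensities are far smaller. It left 31 higher and 52 lower genes, CCN5 at -0.060, and medians of 0.79 for the CCN family, -0.11 for TGF-β targets, -0.46 for epithelial, -0.22 for estrogen receptor target, -0.98 for luminal, 0.26 for mesenchymal and 0.24 for interferon genes. The filter at the 75th percentile left 306 higher and 457 lower genes and medians of 2.90 for the CCN family, -1.13 for TGF-β components, -0.96 for TGF-β targets, -1.40 for estrogen receptor targets, -3.56 for luminal and 2.58 for interferon genes, because fewer genes remained. In that order these medians rested on 1, 4, 3, 6, 7 and 11 genes. Under that filter the mesenchymal median reversed to -0.20, since TPM2 was the only member left. Without a filter the medians were -0.077 for TGF-β targets and 0.62 for interferon genes, and the cause was not tested. Filling empty cells gave 956 higher genes and medians of -0.10 for TGF-β targets, -2.73 for epithelial and -3.44 for estrogen receptor target genes, because genes listed on 1 array then entered. Thresholds of 1.5 on the log2 scale gave 301 and 487 genes, 1.5-fold gave 1262 and 1736, and 2-fold with over 3 times the scatter gave 164 and 296. Of the other comparisons, 528 values of named genes stayed within the scatter and 92 moved, 86 of them with 50 added. Many of the 528 could not move. Median centring shifted every gene alike by less than any scatter or list spread, and the median of probes left genes with 1 probe unchanged. Of the list medians, 212 stayed within the spread of their random lists, 58 moved and 1 reversed, and with unmatched random lists all 34 percentiles stayed inside or outside the central 95% as before, the ribosomal one going from 27.7 to 55.6. Dim probes limit what folds can show, since values under 1.47 were set to the floor.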

Other observations

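Genes of stress, metabolism and chromatin that the report does not describe went several ways. Of 20 hypoxia and glycolysis genes, 2 were at least 2-fold higher on sh-CCN5 and 18 within 2-fold, with a median of 0.49 at the 99.8th percentile of random lists; the enolase gene ENO2 (1.88) and the kinase gene PGK1 (1.10) lay highest, and the glucose transporter gene SLC2A1 (-0.80) and BNIP3L (-0.74) lowest. Of 7 replication-dependent histone genes, 4 were at least 2-fold lower, 1 higher and 2 within 2-fold, with a median of -1.92, below all random lists; H4C8 and H2BC21 both lay at -3.70 and H4C3 at 1.04. Of 12 p53 target genes, 3 were higher, 3 lower and 6 within 2-fold, with a median of -0.79 at the 0.58th percentile, from GADD45A, a growth arrest gene (2.59), and the death receptor gene TNFRSF10B (1.503, or 0.83 as the median of its probes) to the DNA repair gene XPC (-1.98) and SESN1 (-1.62). Of 11 heat shock and metallothionein genes, 2 were higher, 1 lower and 8 within 2-fold, with a median of 0.51 at the 98.9th percentile. Among them the metallothionein gene MT1X (1.38) and the co-chaperone gene DNAJA1 (1.19) lay highest, and the small heat shock gene HSPB1 had intensities of 936 and 197 (-2.25). Of 11 unfolded protein and amino acid stress genes, 3 were higher, 1 lower and 7 within 2-fold (median 0.35, 94.2nd percentile), with the serine synthesis gene PSAT1 at 2.57 and DDIT3 at 1.79 against XBP1 at -3.601. Of 12 cholesterol synthesis genes, 1 was higher, STARD4 (1.87), 2 were lower, SQLE (-2.08) and CYP51A1 (-1.03), and 9 lay within 2-fold (median -0.48, 7.18th percentile).

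The medians of signalling and housekeeping lists, over members at the level filter, stayed inside the central 95% of their random lists. Of 17 apoptosis regulators, 3 were at least 2-fold higher, 2 lower and 12 within 2-fold (median 0.19), with PMAIP1 (5.19) and the inhibitor gene BIRC2 (2.32) against BIK (-2.18) and CASP6 (-2.04). Of 8 growth factor receptors and ligands, 0 were higher, 2 lower and 6 within 2-fold (median 0.09), and the lower ones were the receptor kinases FGFR4 (-3.51) and ERBB2 (-1.99). A further 5 members of the growth factor list were listed on sh-CCN5 alone and 3 on sh-scrambled alone. NF-kB and cytokine genes had a median of -0.04 with 1 higher, 2 lower and 5 within 2-fold, from CXCL8 (4.88) to BCL3 (-1.95) and IL6 (-1.40), and the sign of that median changed with scaling. A further 7 members of that list were listed on sh-CCN5 alone, among them the chemokine gene CXCL2 (18.2) and the cytokine gene IL1A (16.2), named after their values were seen, and 1 on sh-scrambled alone. The Notch list had 1 lower gene, HES1 (-1.996), and 5 within 2-fold (median -0.37). The Wnt list had 1 lower gene, the secreted inhibitor DKK1 (-1.29), and 1 within 2-fold, LEF1 at 0.34 (median -0.48). Histone deacetylases and corepressors had 1 higher gene, HDAC8 (1.49), 1 lower, DNMT3B (-1.24), and 10 within 2-fold (median -0.17). The small RNA machinery had 1 higher gene, DROSHA (1.30), 1 lower, ADAR (-1.33), and 7 within 2-fold (median -0.07, of either sign across scalings). Of 24 ribosomal protein genes 2 were higher, RPS23 (1.16) and RPS15 (1.06), 1 lower, RPS3 (-1.02, with another probe at -0.26), and 21 within 2-fold, with a median of -0.05 that was 0.23 under quantile scaling. Of 18 oxidative phosphorylation genes 1 was higher, NDUFB8 (1.08), 2 lower, COX6C (-3.37) and UQCRC2 (-1.07), and 15 within 2-fold (median -0.20); another probe of COX6C lay at -0.66.

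Markers of other cell types were mostly without a value. Fibroblast markers had 2 genes at the filter, PCOLCE (-2.498) and C1S (0.05), with a median of -1.22. Over the 5 fibroblast markers listed on both arrays, whatever their level, the median was 0.07. The immune list had 1, CD79A at -0.21. The endothelial list had 2, with ESAM, an adhesion molecule, at 4.19 and 95.3 (4.51) and PECAM1 at -0.06, a value that changed sign with quantile and median scaling; their median was 2.22, at the 99.2nd percentile.

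In windows of 41 neighbouring genes, the running median of the difference ran from -1.27 to 0.91, and 40.1% of 5657 windows lay outside the central 95% of shuffled orders, -0.36 to 0.20. The windows overlap and are not independent.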
